A study of Homo sapiens with 24 samples.

How the data were processed

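Polyadenylated RNA of Jurkat cells was sequenced in 24 libraries from 8 groups of 3 (genotype WT or KO, PMA with ionomycin or CD3 and CD28 antibodies, activated or control). Per the labels, RNA was extracted with TRIzol, reverse transcribed with random hexamers, and fragments of 370 to 420 bp were selected. The authors processed reads with fastp, HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3 and DESeq2 1.20.0 on hg38; the fastp version and the annotation release were not given in the sources used here. Sample groups were taken from the sample titles.

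The authors deposited 8 tables of 63241 genes, 1 per comparison, of which 20601 genes had no symbol. Each deposited table held values per library that were handled here like expected counts, that is counts in which a read can be split between genes, because 29.3 to 31.9% of the non-zero values as deposited were not whole. The labels name featureCounts, and how the fractions arose was not given in the sources used here. The authors also gave TPM per sample and the mean TPM of each group. For each comparison the authors gave a ratio (fold change), its log2 value, and a p-value with its adjusted p-value, where a missing p-value appears as 1. The authors called a gene at an adjusted p under 0.05 with an absolute log2 fold change of at least 1. A further 8 deposited tables gave KEGG pathways, with the number of called genes of a pathway, a rich factor that is a fraction (called genes over pathway genes), and a p-value and adjusted p-value for each pathway. Of the per-library columns, 48 recurred in more than 1 table and all 48 were identical. These counts were rounded to whole numbers for the tests. TPM values were not used for tests because they carry no library size.

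Library totals were 16012410 to 22846872 counts, a ratio of 1.43 between the largest and smallest. At this depth 3 counts over a group of 3 libraries, the floor used for groups without counts, equal 0.052 to 0.0565 CPM. Levels in CPM were scaled by TMM over all 24 libraries, while fold changes came from fits of the libraries compared, so a ratio of printed levels can differ slightly from the printed fold. Positions and transcript lengths came from GENCODE v29 on GRCh38.

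Analyses ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The main test was the edgeR quasi-likelihood F test on TMM-scaled counts after filterByExpr with a minimum count of 10, using only the libraries compared. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values of single genes are from edgeR with that adjustment throughout. The comparisons were activated against control cells (4), KO against WT cells (4), PMA against CD3 in activated cells (2) and in control cells (2), and 4 interaction terms. The common biological coefficient of variation was 0.0334 to 0.0424, but 0.100 to 0.102 in pairwise comparisons with activated KO cells of the PMA experiment, and 0.0761 and 0.0782 in the interactions that hold them (genotype with PMA and stimulus in KO cells). Before the data were examined, 32 gene lists were fixed. Lists with at least 5 tested genes were tested with camera (limma), estimating the correlation between genes in each list, and adjusted over the lists of a comparison. List counts were also adjusted over the list alone. The sets of markers of B cells, myeloid cells, erythroid cells and megakaryocytes, and epithelial cells and fibroblasts had under 5 tested genes and served to look for other cell types. In activated against control WT cells of the PMA experiment 1 of 2 B cell markers fell, 2 of 3 myeloid markers rose and 1 fell, and 2 of 3 epithelial and fibroblast markers rose and 1 fell. In the same comparison of KO cells none of 2 B cell markers was called, 3 of 4 myeloid markers rose (median 2.53), and 2 of 3 epithelial and fibroblast markers rose and 1 fell. Between activated KO cells of PMA and CD3, 3 of 4 myeloid markers were higher with PMA and 1 lower (median 1.85). Between activated KO and WT cells of the CD3 experiment the only tested erythroid and megakaryocyte marker was higher in KO (log2 fold change 5.89), and 2 of 3 B cell markers were lower. Summed over all these markers, libraries held 111 to 171 CPM, with 165 to 171 CPM in WT CD3 controls, 132 to 142 CPM in activated WT cells of that experiment and 121 to 126 CPM in WT PMA controls.

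Genes were named by rules. In each comparison the 8 largest rises and 8 largest falls were taken among protein-coding genes with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the groups. For lists, the 2 to 4 largest passing members were taken. For all 4 KO against WT comparisons, 10 genes higher and 10 lower were ranked by the smallest of the 4 absolute log2 fold changes. IL2, CD69, IL2RA, EGR1, NR4A1, CD3E, CD247, MYC and GAPDH were looked up in every comparison. A group without counts was set to the floor and the fold given as at least that value. With 1 to 3 counts in a group, the ratio of counts is given with its 95% counting interval in place of a fitted fold. Reads of near copies, such as XCL1 and XCL2, CCL3 and CCL4 with their copies, HSPA1A and HSPA1B, and the HLA genes, can be assigned to the wrong member.

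The tests were tested on simulated data with the library sizes and dispersion of the data. In these, set genes were changed 1.5-fold, 2-fold or 4-fold, with 63 to 67 tested genes for each fold. For activated against control WT cells of the PMA experiment 66.2%, 83.6% and 100% of them were recovered, with 8.99% false calls. For KO cells of the CD3 experiment these were 65.7%, 92.5% and 97.0%, with 9.57% false calls. For KO against WT controls of the PMA experiment they were 59.7%, 86.4% and 100%, with 4.68% false calls, and for the interaction of genotype with CD3 stimulation 55.2%, 66.7% and 92.3%, with 5.37%. Recovered genes had the right sign in 100% of cases. A shifted list was found at camera p-values of 1.41e-06, 6.61e-06, 9.66e-06 and 7.41e-10, and unchanged lists gave 0.391 to 0.968. Genes were drawn independently of each other, so the list test was not tried on correlated genes such as those of the data. The share of false calls was thus above the nominal 5% in 3 of the 4 simulations. Each simulation gave 149 to 188 calls, whereas the same 4 comparisons of the data gave 2000 to 10941. These shares therefore do not carry over directly to the data. Activated KO cells of the PMA experiment, whose comparisons had a larger spread, were in none of the simulations.

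Alternatives fixed before the data were examined were DESeq2, median-of-ratios scaling, library size alone, no count filter, 1 fit of all 24 libraries, the replicate number as a block, each library left out in turn, a preset list correlation of 0.01, and for correlations across genes a mean of at least 5 CPM. Removal of each library's trend with transcript length and GC content was added after seeing the data. The labels did not say that replicate numbers pair samples, so no block entered the main fits. Deviations of same-numbered libraries from their groups correlated at -0.199 to 0.181 between groups. In KO cells of the CD3 experiment (0.099 to 0.181) and between WT controls (0.046 to 0.157) each library matched its own number best. This did not hold throughout any other comparison. Deposited TPM and pathway tables were used only for checks and for the values cited from them. Raw reads were not used here. Single-gene results for 3 genes are not reported here.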

Results

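Messenger RNA of Jurkat cells, an established human T-cell leukaemia line, was sequenced in 24 libraries. The labels gave 2 genotypes, wild type (WT) and knockout (KO), 2 stimuli, and an activated and a control state, with 3 libraries in each of the 8 groups. PMA with ionomycin bypasses the T-cell receptor by acting on protein kinase C and calcium, whereas antibodies against CD3 and CD28 (5 and 2 µg/mL) engage the receptor itself. Both treatments lasted 24 h. The labels stated 0.16 and 2.6 mM for PMA and ionomycin, but the stated stocks of 320 µM and 5.2 mM diluted 2000-fold give the same figures in µM. Whether control cells received the solvent was not stated. The gene knocked out was not named in the labels, so a fall of its own transcript was not checked. Each stimulus had its own control groups, called here PMA controls and CD3 controls.

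Libraries held 16012410 to 22846872 counts. Activated and control WT cells of the PMA experiment held 17354649 to 19274236 and 16012410 to 22846872 counts per library, and the matching KO groups 16012891 to 17863225 and 16070422 to 21637731. In the CD3 experiment WT cells held 17635886 to 19332705 and 17942942 to 19406775, and KO cells 16819047 to 19327022 and 16201698 to 20410328. Levels are given as CPM (counts scaled by library size, mean ± SD, n = 3 libraries), and log2 fold changes come with their SE from edgeR fits of 3 against 3 libraries. The origin of the replicates was not stated, so p-values measure the spread between these samples, which may be technical. Intervals of count ratios and detection floors of 3 counts per group (0.052 to 0.0565 CPM) cover counting error only. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and gene positions are on GRCh38 with the GENCODE v29 annotation.

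Activated PMA libraries stood apart from all others on the first principal component, which carried 71.9% of the variance of 11017 genes, while the next component (11%) separated WT from KO. Mitochondrially encoded transcripts made up 3.15 ± 0.155% of counts in activated WT and 3.16 ± 0.506% in activated KO cells of the PMA experiment, against means of 4.37 to 4.71% in the other groups (n = 3 each). Replicates of a group correlated at 0.995 to 0.997 across genes, except for pairs with replicate 2 of activated KO cells in the PMA experiment (0.977 to 0.979). That library differed from its group by transcript length, with short transcripts higher and long transcripts lower. Of 10 bins by length, genes of the shortest had a median 0.377 log2 above, and those of the longest a median of -0.411 log2 from, their mean in the other 2 replicates. It was kept in all main results.

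**Figure D1:**
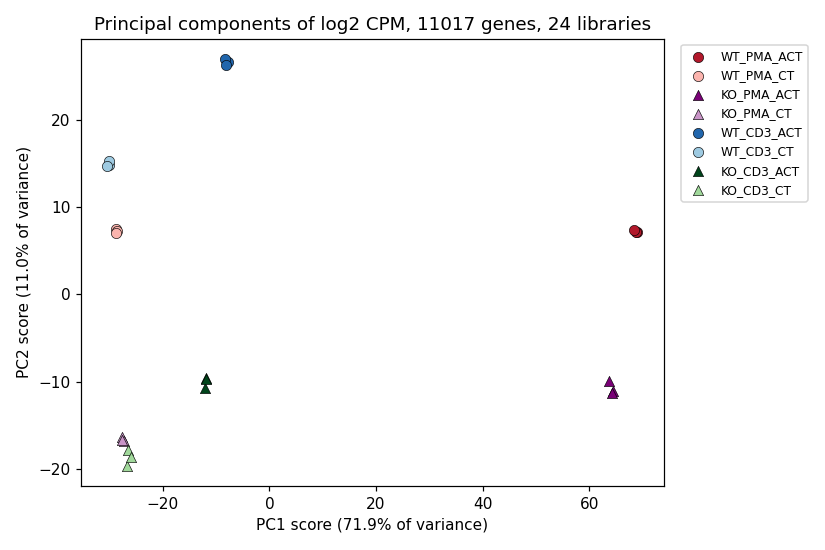
Principal components of log2 CPM of 11017 genes in 24 libraries, 1 point per library, with the share of variance on each axis and colours for the 8 groups. Activated PMA groups lie far right on the first component (71.9%).

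**Figure D2:**
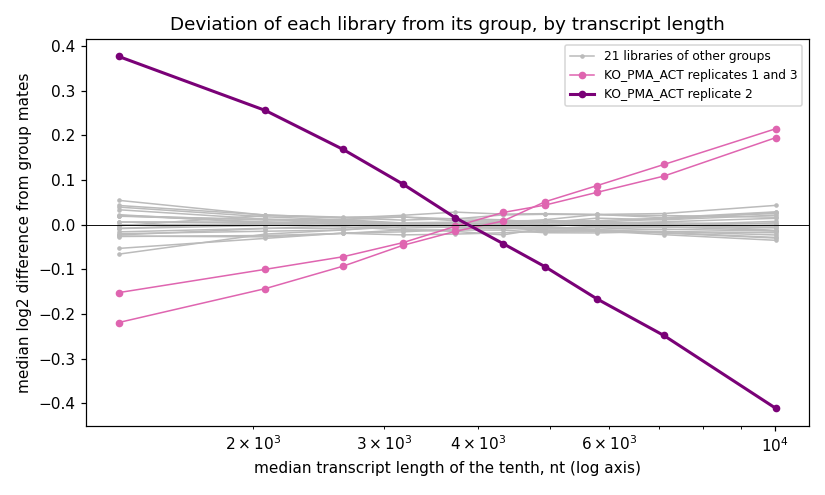
Median log2 difference of each library from its group mates in 10 bins of transcript length, 1 line per library. Replicate 2 of activated KO cells in the PMA experiment runs from 0.377 in the shortest to -0.411 in the longest bin.

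Activated WT cells of the PMA experiment switched on cytokine genes that control cells did not express. XCL1, a lymphocyte chemokine (chromosome 1, 168576473–168582077), reached 877 ± 29 CPM from 0 counts, a rise of at least 16900-fold, and its neighbour XCL2 reached 510 ± 13.9 CPM (at least 9810-fold), although reads of this pair are hard to tell apart. CCL4 and CCL3, chemokines that draw macrophages and T cells (chromosome 17, 36103590–36105621 and 36088256–36090169), rose at least 7450-fold to 387 ± 11.4 CPM and at least 3320-fold to 172 ± 7.16 CPM, with reads shared by near copies. IL3, a growth factor of blood cells, rose at least 5760-fold to 299 ± 2.61 CPM. IL2, the T-cell growth factor (chromosome 4, 122451470–122456725), rose from 0.0338 to 573 ± 4.01 CPM, a count ratio of 16500 (4580–137000). Of 27 tested cytokine genes 24 rose and 1 fell, also when adjusted over the list alone, with a median log2 fold change of 7.30, or 5.67 with genes at 0 counts taken at their bound (camera adjusted p = 0.0257 with an estimated correlation). Lower in activated cells were genes of early T-cell development. DNTT, the enzyme that adds nucleotides at receptor joints, fell from 119 ± 2.3 to 0.96 CPM (-6.92 ± 0.074), RAG2, part of the recombinase, fell by 6.43 ± 0.24, and TCF7, a factor of T-cell identity, fell from 470 ± 6.75 to 17.2 ± 1.47 CPM (-4.74 ± 0.044). Of 35 thymocyte and lineage genes 27 fell and 6 rose, alike when adjusted over the list alone (adjusted p = 0.0190 with an estimated correlation). Those that rose included TBX21, the driver of type 1 helper cells (6.85 ± 0.14), and LMO2 (count ratio 379, 105–3140).

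Surface receptors and early transcription factors rose in the same WT cells after PMA and ionomycin (n = 3 per group). CD69, an early activation marker (chromosome 12, 9752486–9760901), rose from 12 ± 0.664 to 607 ± 4.59 CPM (5.67 ± 0.04). IL2RA, the high-affinity IL-2 receptor chain, reached 41.3 ± 1.55 CPM at a count ratio of 794 (271–3850), and TNFRSF9, a co-stimulatory receptor, 336 ± 6.32 CPM at 19400 (3480–766000). Of 32 activation receptors 21 rose and 11 fell, with the same counts adjusted over the list alone (adjusted p = 0.0387 with an estimated correlation). EGR1, an immediate early factor, rose by 6.26 ± 0.056, and NR4A1, an orphan receptor induced by receptor signals, by 4.16 ± 0.07. EGR2 and NR4A2 rose at least 2740-fold and at least 3540-fold from 0 counts. In the immediate early list 28 of 32 rose and 3 fell (28 and 3 adjusted over the list alone; adjusted p = 0.0296 with an estimated correlation). Among 23 feedback genes of the ERK kinase 20 rose and 1 fell (21 and 1 adjusted over the list alone; adjusted p = 0.0296 with an estimated correlation), led by PHLDA1 (7.35 ± 0.096) and DUSP4, an ERK phosphatase (count ratio 538, 184–2610). Targets of NF-kB followed, with 23 of 28 higher and 3 lower, also adjusted over the list alone (adjusted p = 0.0257 with an estimated correlation). BCL2A1, a survival gene, rose by 10.08 ± 0.18, TRAF1 by 6.54 ± 0.069 and RELB by 5.06 ± 0.16. Among T-cell receptor genes TRAC rose by 4.10 ± 0.037, while THEMIS and SH2D1A fell by 3.82 ± 0.053 and 2.54 ± 0.037. That list split into 14 higher and 20 lower of 34 (also adjusted over the list alone) and was not called (adjusted p = 0.341 with an estimated correlation). CD247, a receptor signalling chain, fell by 1.08 ± 0.036, and CD3E moved by only 0.13 ± 0.025.

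Interferon-stimulated genes all rose in activated WT cells of the PMA experiment, 40 of 40 and also 40 when adjusted over the list alone, with a median of 2.47 (adjusted p = 0.0190 with an estimated correlation, n = 3 per group). The guanylate-binding GTPases GBP2 and GBP5 reached 682 and 1000 CPM (12.40 ± 0.077 and 9.69 ± 0.074), and IFI44L reached 82.4 CPM at a count ratio of 2380 (657–19600). Antigen presentation genes rose in 18 of 19 cases, likewise adjusted over the list alone (median 2.00; adjusted p = 0.0138 with an estimated correlation). HLA-B rose from 86.8 to 1260 CPM (3.88 ± 0.037) and HLA-E by 3.67 ± 0.034, with reads partly shared among HLA genes. Cytotoxic genes rose in 8 of 9 cases, also adjusted over the list alone (adjusted p = 0.0246 with an estimated correlation), among them GZMB, a killer protease (10.11 ± 0.12). Sterol synthesis rose in 22 of 25 genes and fell in 2, as it did adjusted over the list alone (median 1.11; adjusted p = 0.0121 with an estimated correlation). HMGCS1, which makes the precursor of mevalonate, rose from 571 to 2240 CPM (1.99 ± 0.022) and CYP51A1 by 2.96 ± 0.098. ASNS, the asparagine synthetase, rose by 4.20 ± 0.042 and TRIB3, a stress kinase relative, by 2.99 ± 0.051. Of 28 amino acid response genes 25 rose and 2 fell, the same adjusted over the list alone (adjusted p = 0.0296 with an estimated correlation). Chaperones of the endoplasmic reticulum rose in 20 of 23 and fell in 2, and apoptosis regulators in 25 and 7 of 36 (20 and 2, and 25 and 8, adjusted over the list alone; adjusted p = 0.0268 and 0.0246 with an estimated correlation).

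Proliferation genes fell in activated WT cells of the PMA experiment. UHRF1, which maintains DNA methylation at replication, fell from 353 to 120 CPM (-1.53 ± 0.032), and CDC20, which starts the exit from mitosis, from 149 to 38.1 CPM (-1.94 ± 0.049). Of 40 replication genes 39 fell and 1 rose, and all 38 mitotic genes fell, with identical counts adjusted over the list alone (adjusted p = 0.0190 and 0.0399 with an estimated correlation). MYC, the growth regulator, fell from 314 to 141 CPM (-1.13 ± 0.03). CDKN1A, the p21 inhibitor, rose by 4.73 ± 0.15 and BTG1 by 3.53 ± 0.051, yet of 25 cell cycle inhibitors 13 rose and 9 fell, also adjusted over the list alone (adjusted p = 0.461 with an estimated correlation). HSP90AA1, a cytosolic chaperone, fell by 1.41 ± 0.026, and 15 of 17 heat shock genes were lower, also adjusted over the list alone (adjusted p = 0.0546 with an estimated correlation). MT-ND3 and MT-CYB fell by 1.36 ± 0.034 and 1.24 ± 0.034. Of 13 mitochondrially encoded genes 11 fell and 1 rose (11 and 1 adjusted over the list alone; adjusted p = 0.261 with an estimated correlation), and of 43 nuclear respiratory genes 36 fell and 3 rose (36 and 3 adjusted over the list alone; adjusted p = 0.350 with an estimated correlation). Inhibitory checkpoint genes split into 19 higher and 7 lower of 31, also adjusted over the list alone (adjusted p = 0.0931 with an estimated correlation), and CD200, an inhibitory ligand, reached 446 CPM at a count ratio of 25800 (4620–1.02e+06). No call was made for calcium signalling, glycolysis and fatty acid synthesis, in which 14, 13 and 10 of 30, 24 and 13 genes rose and 11, 9 and 2 fell (adjusted p = 0.937, 0.417 and 0.299 with an estimated correlation). NFATC1, the calcium-driven factor, rose by 2.90 ± 0.041 and PKM, a glycolytic kinase, by 1.56 ± 0.019. Hypoxia and oxidative stress genes rose in 8 and fell in 10 of 25, ribosome biogenesis in 7 and 24 of 34, and ribosomal proteins in 12 and 22 of 58 (adjusted p = 0.372, 0.204 and 0.928 with an estimated correlation). Adhesion genes rose in 21 and fell in 14 of 38, with a median of 0.15 although the test leaned down (adjusted p = 0.341 with an estimated correlation).

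In all, edgeR called 10941 of 15707 tested genes between activated and control WT cells of the PMA experiment, 5606 higher and 5335 lower, of which 2159 and 961 moved at least 2-fold. With all 6 libraries 15 lists passed. Without control replicate 2 this fell to 3, without activated replicate 3 to 5 and without activated replicate 1 to 6. It was 11 without activated replicate 2, 13 without control replicate 1 and 14 without control replicate 3. Only sterol synthesis and antigen presentation kept their calls each time (highest adjusted p = 0.041 for both).

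**Figure D3:**
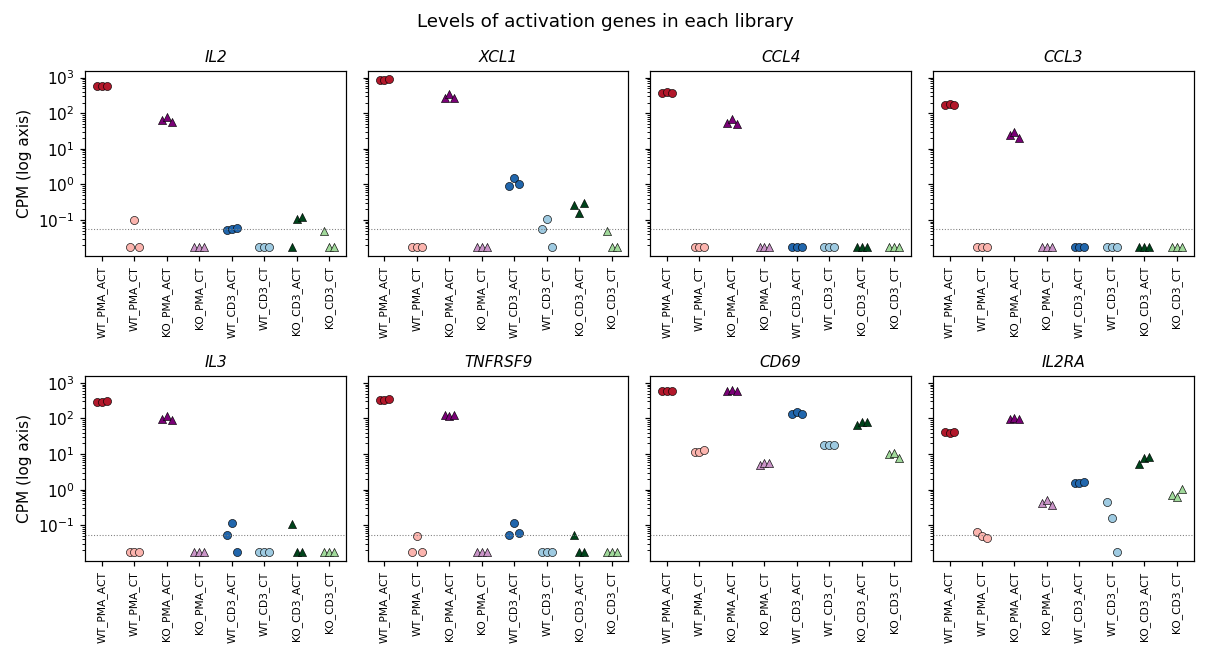
CPM on a log axis of IL2, XCL1, CCL4, CCL3, IL3, TNFRSF9, CD69 and IL2RA, 1 point per library in 8 groups. The dotted line is the mean detection floor, libraries with 0 counts are drawn at the bottom, and IL2 stands at 573 CPM in activated WT against 66.7 CPM in activated KO cells of the PMA experiment.

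KO cells also switched on cytokine genes after PMA and ionomycin. XCL1 and XCL2 reached 291 ± 47.5 and 157 ± 29.4 CPM from 0 counts (at least 5460-fold and 2940-fold), IL3 101 ± 14.2 CPM (at least 1880-fold), and IL2 66.7 ± 9.69 CPM (at least 1250-fold). TNFRSF9 reached 124 ± 3.95 CPM (at least 2320-fold) and CD200 71.4 ± 4.54 CPM (at least 1340-fold). Of 25 cytokine genes 23 rose, as they did adjusted over the list alone (median 6.49, or 6.11 at the bound; adjusted p = 0.0270 with an estimated correlation). CD69 rose from 5.28 ± 0.379 to 618 ± 20.4 CPM (6.91 ± 0.09), IL2RA to 97.8 ± 5.07 CPM (7.85 ± 0.12), EGR1 by 5.58 ± 0.086 and NR4A1 by 5.55 ± 0.095. TRAC, the receptor alpha constant gene, rose by 5.27 ± 0.13. Receptors of activation rose in 24 and fell in 7 of 32, and immediate early genes rose in 29 and fell in 1 of 32, both unchanged adjusted over the list alone (adjusted p = 0.0270 and 0.0149 with an estimated correlation). EGR2 rose by 9.36 ± 0.18 and NR4A3 by 7.94 ± 0.17. ERK feedback genes rose in 20 and fell in 1 of 23 (20 and 1 adjusted over the list alone; adjusted p = 0.00391 with an estimated correlation), with IER3 and PHLDA1 at 6.58 ± 0.15 and 6.52 ± 0.083. DNTT fell by 5.34 ± 0.13, RAG2 by 5.20 ± 0.14, RAG1 by 4.30 ± 0.17, and ADA, an adenosine-clearing enzyme of thymocytes, by 3.96 ± 0.1. Thymocyte genes fell in 23 and rose in 11 of 36 (24 and 11 adjusted over the list alone; adjusted p = 0.0144 with an estimated correlation).

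Interferon-stimulated genes rose in 38 of 39 KO cases after PMA and ionomycin, also adjusted over the list alone (median 2.55; adjusted p = 0.00391 with an estimated correlation), with GBP2 at 375 CPM (11.51 ± 0.13). HLA-B rose by 4.85 ± 0.1, in a presentation list with 18 of 19 higher, also adjusted over the list alone (adjusted p = 0.0230 with an estimated correlation). HMGCS1 rose from 195 to 1340 CPM (2.82 ± 0.074) and MSMO1 by 2.34 ± 0.063, and sterol synthesis rose in 23 and fell in 1 of 25 (23 and 1 adjusted over the list alone; adjusted p = 0.00617 with an estimated correlation). UHRF1 fell by 2.00 ± 0.063, KIF20A by 1.91 ± 0.077 and MYC by 1.67 ± 0.088. Replication genes fell in 39 and rose in 1 of 40, and all 38 mitotic genes fell, with the same counts adjusted over the list alone (adjusted p = 0.00391 and 0.00401 with an estimated correlation). PDCD1, the PD-1 receptor, reached 30.9 CPM at a count ratio of 576 (197–2800). Checkpoint genes rose in 20 and fell in 4 of 30 (20 and 5 adjusted over the list alone; adjusted p = 0.00752 with an estimated correlation). Receptor-complex genes split evenly, with 14 higher and 14 lower of 34, also adjusted over the list alone (adjusted p = 0.271 with an estimated correlation). EdgeR called 8678 of 15688 genes, 4646 higher and 4032 lower, or 5558 and 3204 when scaled by library size alone. With 15 lists called, leaving out activated replicate 1 ended the cytokine call (adjusted p up to 0.056 over the libraries), as did control replicate 3. Activation receptors lost theirs without activated replicate 3 or control replicate 1 or 3 (up to 0.065). Apoptosis regulators lost theirs without activated replicate 2 or 3 (up to 0.091), and cytotoxic genes on leaving out any 1 library except activated replicate 2 (up to 0.067).

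Stimulation through CD3 and CD28 moved fewer genes than PMA and ionomycin in WT cells. PDCD1 rose by 5.73 ± 0.28 to 10.3 CPM, HDC, the histamine-forming enzyme, by 5.57 ± 0.23, and LGALS1, a galectin that dampens T cells, by 5.01 ± 0.16. ZBTB16, a factor of innate-like T cells, rose from 8.64 to 137 CPM (3.99 ± 0.058). CD69 rose from 17.7 ± 0.331 to 138 ± 11.6 CPM (2.97 ± 0.062), EGR1 by 3.03 ± 0.1, and IL2RA by 2.90 ± 0.52 to 1.57 CPM. IL2 stayed at the detection floor. CCR7, a homing receptor, rose by 3.49 ± 0.2, ICOS by 3.31 ± 0.24 and CD27 by 3.08 ± 0.21. Activation receptors rose in 20 and fell in 6 of 29, the same adjusted over the list alone (adjusted p = 0.0102 with an estimated correlation). Checkpoint genes rose in 18 and fell in 3 of 29 (19 and 3 adjusted over the list alone; adjusted p = 0.00994 with an estimated correlation), among them BTLA (4.13 ± 0.53), TOX2, an exhaustion-linked factor (3.32 ± 0.12), and CD244 (2.14 ± 0.11). TRAC rose from 95.7 ± 1.86 to 582 ± 15.4 CPM (2.62 ± 0.031), LCP2, an adaptor, by 1.74 ± 0.03, and CD28 by 1.39 ± 0.026. Receptor-complex genes rose in 19 and fell in 6 of 34 (19 and 7 adjusted over the list alone; adjusted p = 0.00994 with an estimated correlation). Immediate early genes rose in 19 and fell in 2 of 28, unchanged adjusted over the list alone (adjusted p = 0.0219 with an estimated correlation), led by EGR3 (4.95 ± 0.38) and NR4A3 (3.08 ± 0.27).

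Ribosome biogenesis and heat shock genes fell in CD3-stimulated WT cells (n = 3 per group). RAG2 fell by 3.91 ± 0.17, DNTT from 166 to 15.2 CPM (-3.44 ± 0.053), RAG1 by 3.22 ± 0.11 and MYC from 359 to 176 CPM (-1.02 ± 0.031), but of 34 thymocyte genes 16 rose and 12 fell (17 and 14 adjusted over the list alone; median 0.14; adjusted p = 0.873 with an estimated correlation). BOP1, a ribosome assembly factor, fell by 0.89 ± 0.045 and NPM1 by 0.53 ± 0.027. Ribosome biogenesis genes fell in 33 and rose in 1 of 34, the same adjusted over the list alone (median -0.38; adjusted p = 0.00994 with an estimated correlation). Heat shock genes fell in 14 of 17, also adjusted over the list alone (adjusted p = 0.0196 with an estimated correlation), HSPD1 by 0.60 ± 0.024. Adhesion and migration genes rose in 27 and fell in 2 of 37 (27 and 3 adjusted over the list alone; adjusted p = 0.00994 with an estimated correlation), ITGB7 by 1.49 ± 0.2. GZMA, a granzyme, rose by 2.60 ± 0.071, and 6 of 7 cytotoxic genes rose, likewise adjusted over the list alone (adjusted p = 0.0276 with an estimated correlation). Cytokine genes rose in 6 of 10, as they did adjusted over the list alone (adjusted p = 0.0571 with an estimated correlation), with IL16 from 13 to 76.8 CPM (2.58 ± 0.062). Interferon-stimulated genes rose in 18 and fell in 6 of 37 (adjusted p = 0.0672 with an estimated correlation), sterol genes rose in 20 and fell in 3 of 25 (adjusted p = 0.0624), and 33 of 38 mitotic genes fell (adjusted p = 0.122). Ribosomal protein genes fell in 55 of 58 by a median of -0.24 (adjusted p = 0.358 with an estimated correlation). GAPDH and CD247 were not called (edgeR Benjamini-Hochberg adjusted p = 0.238 and 0.0575). EdgeR called 6741 of 14856 genes, 3440 higher and 3301 lower, of which 568 and 175 moved 2-fold. Immediate early genes lost their call without activated replicate 1 or 2 (adjusted p up to 0.065), and cytotoxic genes on leaving out any 1 of the 6 libraries (up to 0.077).

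KO cells under CD3 and CD28 antibodies had the fewest calls of the 4 stimulations. HDC rose by 4.99 ± 0.2 to 13.5 CPM, EGR1 by 3.78 ± 0.1, ENPP1, an ecto-enzyme, by 3.72 ± 0.11, LGALS1 by 3.59 ± 0.1, and CD69 from 9.63 ± 1.47 to 73.5 ± 7.02 CPM (2.94 ± 0.089). IL2RA rose by 3.15 ± 0.24 to 7.0 CPM and NR4A1 by 1.57 ± 0.15. RAG1 fell from 101 to 19.1 CPM (-2.41 ± 0.052), DNTT by 2.00 ± 0.077, RAG2 by 1.89 ± 0.082 and MYC by 0.59 ± 0.035. TRAC rose from 28.6 ± 2.56 to 189 ± 3.5 CPM (2.72 ± 0.05), LCP2 by 1.27 ± 0.033 and CD28 by 1.18 ± 0.033. Receptor-complex genes rose in 18 and fell in 4 of 34 (20 and 5 adjusted over the list alone; adjusted p = 0.0280 with an estimated correlation). Activation receptors rose in 19 and fell in 3 of 29, and immediate early genes rose in 20 and fell in 1 of 28, both unchanged adjusted over the list alone (adjusted p = 0.00420 and 0.00475 with an estimated correlation). EGR2 rose by 4.16 ± 0.41. Checkpoint genes rose in 17 and fell in 2 of 28 and adhesion genes in 28 and 1 of 37 (17 and 3, and 29 and 1, adjusted over the list alone; adjusted p = 0.00420 with an estimated correlation for each), TOX2 by 2.07 ± 0.28 and ANXA1 by 1.06 ± 0.044. ERK feedback genes rose in 15 of 21, with ETV5 at 2.46 ± 0.098, antigen presentation in 11 of 17, with HLA-B at 1.08 ± 0.045, and cytotoxic genes in 6 of 9, with GZMA at 2.21 ± 0.067 (15, 13 and 6 adjusted over the list alone; adjusted p = 0.0160, 0.0231 and 0.0172 with an estimated correlation). NF-kB targets rose in 10 and fell in 2 of 26, and cytokine genes rose in 4 of 8 (12 and 2, and 4, adjusted over the list alone; adjusted p = 0.0327 and 0.0447 with an estimated correlation). Ribosome biogenesis genes fell in 19 and rose in 2 of 34 (adjusted p = 0.294 with an estimated correlation). EdgeR called 3450 of 15337 genes, 1832 higher and 1618 lower. With 10 lists called, 5 were called without control replicate 2, 6 without activated replicate 1 or 2, 7 without activated replicate 3 and 8 without control replicate 1 or 3. Activation receptors, checkpoints, immediate early and adhesion genes kept their calls throughout.

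Set side by side, genes moved mostly in the same direction in WT and KO cells under each stimulus, though not always by the same amount. Log2 fold changes correlated at 0.92 across genes after PMA and at 0.73 after CD3 stimulation, where genes are not independent replicates. After PMA 3733 genes rose and 3514 fell in both genotypes, against 1583 and 1388 if the calls were independent, and 167 moved in opposite directions. After CD3 stimulation 1505 rose and 1274 fell in both, against 419 and 361. The slope of KO on WT folds, taken only over genes called in WT cells, was 0.86 and 0.58. A test of the interaction of genotype and stimulation called 2718 of 16598 genes for PMA (1375 up, 1343 down in KO relative to WT), or 4192 without replicate 2 of activated KO cells, and 2000 of 15844 for CD3 stimulation (913 and 1087). The balance of the latter turned with median-of-ratios scaling (1027 up, 998 down), DESeq2 (1095 and 1018) and no count filter (1147 and 936), and that for PMA with these settings (1279 and 1480, 1230 and 1617, and 1450 and 1498 in the same order), in 1 fit of all 24 libraries (1678 and 2086) and without replicate 1, 2 or 3 of activated KO cells (1312 and 1348, 2052 and 2140, 1472 and 1475). That for CD3 stimulation also turned without KO control replicate 1 or 2 (948 and 941, 1023 and 828). With length and GC trends removed it was 995 and 985 for CD3 stimulation and 1804 and 1979 for PMA. TCF7 fell from 470 to 17.2 CPM in WT but only to 80.1 CPM in KO cells after PMA, and receptor-complex genes had 23 positive and 4 negative terms of 34 (24 and 5 adjusted over the list alone; adjusted p = 8.65e-05 with an estimated correlation). Cytokine genes had 3 of each sign in 27, with a median of -1.03 although the test leaned up (adjusted p = 0.794 with an estimated correlation). In the PMA responses 12 of 27 cytokine genes in WT and 10 of 25 in KO cells had a group with 0 counts. The size of their response cannot be measured, so this test does not show an equal cytokine response in both genotypes. Between stimuli the correlation was 0.59 in WT and 0.62 in KO cells. In WT cells 2011 genes rose and 2237 fell with both stimuli, against 1145 and 1195 if independent, and 1257 were opposed, while 267 were opposed in KO cells. Each response was measured against its own controls, and a test of the difference between the responses to PMA and to CD3 antibodies called 8086 of 16175 genes in WT and 6643 of 16460 in KO cells.

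**Figure D4:**
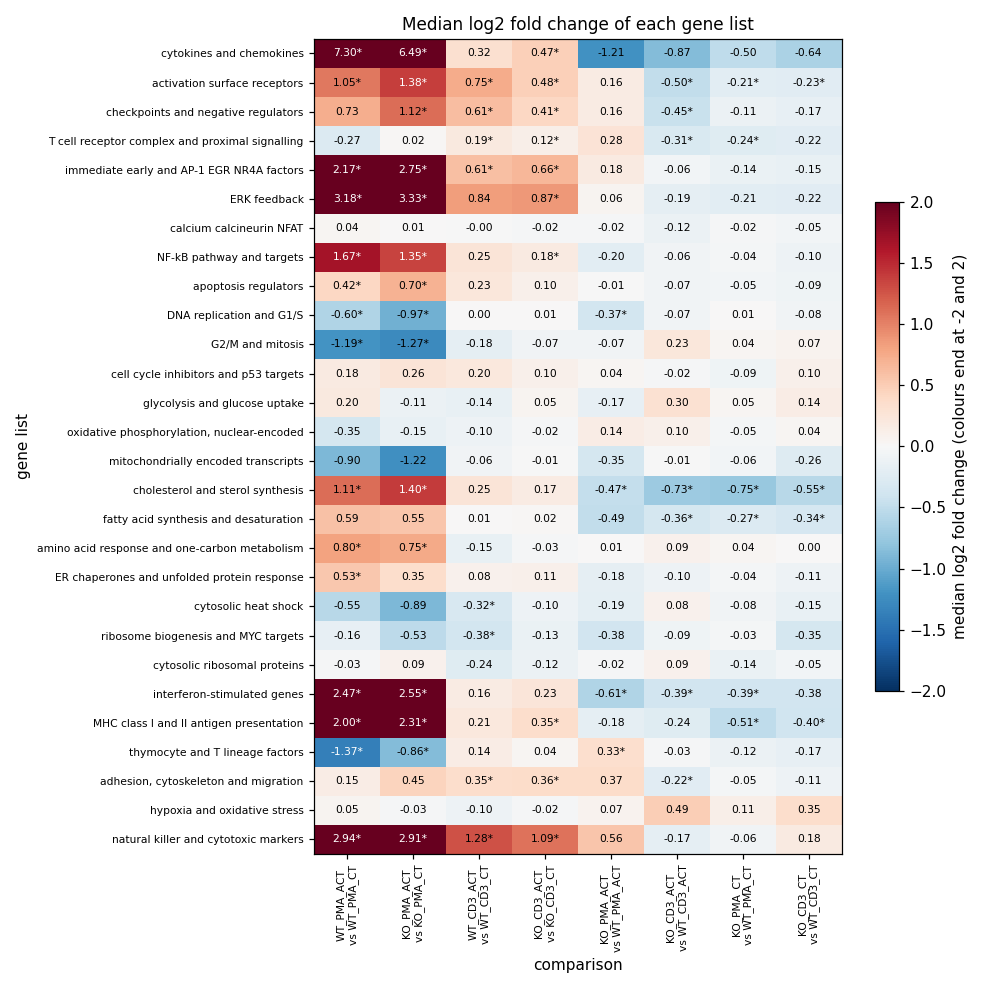
Median log2 fold change of each gene list (rows of the map) in 8 comparisons (columns), with an asterisk where the camera adjusted p was under 0.05. Interferon-stimulated genes rose with PMA in WT (2.47) and KO (2.55) cells, and sterol genes were lower in KO than in WT cells in 4 columns.

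Before stimulation, KO cells of the PMA experiment already differed from WT. NRIP1, a nuclear receptor corepressor (chromosome 21, 14961235–15065936), stood at 46.8 ± 1.01 CPM in KO and 0.516 ± 0.0835 in WT controls (6.48 ± 0.11). RORB, an orphan nuclear receptor (chromosome 9, 74497365–74693177), was at 107 against 9.10 CPM (3.56 ± 0.052), EPHA3, an ephrin receptor, at 73.0 against 5.28 CPM (3.76 ± 0.088), and WT1, a zinc finger factor, was higher by 3.10 ± 0.17. RAG1 was higher by 1.92 ± 0.054 while DNTT was lower at -1.97 ± 0.048. HMGCS1 stood at 195 ± 5.85 against 571 ± 9.46 CPM (-1.55 ± 0.029), and MVD was lower at -1.15 ± 0.054. Sterol genes were lower in 24 and higher in 1 of 25, also adjusted over the list alone (median -0.75; adjusted p = 0.00550 with an estimated correlation). FASN and SCD, of fatty acid synthesis, were lower at -0.93 ± 0.038 and -0.84 ± 0.023, in a list with 9 lower and 1 higher of 12, the same adjusted over the list alone (adjusted p = 0.00892 with an estimated correlation). TRAC was lower at -1.29 ± 0.06 and ZAP70, the receptor kinase, at -0.59 ± 0.037. Receptor-complex genes were lower in 21 and higher in 4 of 34 (22 and 4 adjusted over the list alone; adjusted p = 0.00892 with an estimated correlation). HLA-B was lower at -1.19 ± 0.053 and PSMB10, an immunoproteasome subunit, at -1.28 ± 0.075. Presentation genes were lower in 13 and higher in 1 of 18, also adjusted over the list alone (adjusted p = 0.00892 with an estimated correlation). CD69 was lower at -1.19 ± 0.11 in KO controls, and activation receptors were lower in 14 and higher in 4 of 28 (14 and 5 adjusted over the list alone; adjusted p = 0.0288 with an estimated correlation). Interferon-stimulated genes were lower in 20 and higher in 3 of 36 (21 and 3 adjusted over the list alone; adjusted p = 0.0318 with an estimated correlation), with GBP1 at -1.32 ± 0.068. The call for activation receptors was lost on leaving out any 1 library except WT replicate 1 (adjusted p up to 0.092), and that for interferon-stimulated genes without WT replicate 2 or 3 or KO replicate 1 or 2 (up to 0.14). EdgeR called 4115 of 15072 genes, 2125 higher and 1990 lower in KO.

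Controls of the CD3 experiment gave a similar picture. NRIP1 stood at 48.0 ± 1.99 CPM in KO and 0.556 ± 0.396 in WT (6.46 ± 0.16), RORB at 140 against 5.06 CPM (4.81 ± 0.07), EPHA3 was higher by 4.60 ± 0.083 and KIT, a stem cell factor receptor, by 3.47 ± 0.18. BLK, a kinase mostly of B cells, was lower at -2.12 ± 0.12, PSMB10 at -1.54 ± 0.062, and HMGCS1 stood at 235 against 541 CPM (-1.19 ± 0.031). SQLE was lower at -1.02 ± 0.033. Sterol genes were lower in 23 of 25, as they were adjusted over the list alone (median -0.55; adjusted p = 0.0167 with an estimated correlation). TRAC was lower at -1.72 ± 0.053, MYC at -0.51 ± 0.032 and CD69 at -0.87 ± 0.1, while RAG1 was higher by 2.24 ± 0.051 and RAG2 by 1.71 ± 0.067. Activation receptors were lower in 17 and higher in 6 of 29, and presentation genes in 12 and 2 of 17, without change adjusted over the list alone (adjusted p = 0.0272 and 0.0485 with an estimated correlation). Fatty acid genes were lower in 9 and higher in 1 of 12 (9 and 2 adjusted over the list alone; adjusted p = 0.0485 with an estimated correlation). Ribosome biogenesis genes were lower in 32 of 34, receptor-complex genes in 20 with 8 higher of 34, and interferon-stimulated genes in 19 with 6 higher of 36 (adjusted p = 0.0587, 0.0587 and 0.0681 with an estimated correlation). EdgeR called 7038 of 15097 genes, 3470 higher and 3568 lower. The 4 list calls were not stable when 1 library was left out, which also leaves fewer samples. The sterol call was lost without WT replicate 1 or 2 or KO replicate 2 (adjusted p up to 0.069), activation receptors (0.078) and fatty acid genes (0.13) on leaving out any 1 library except KO replicate 1, and presentation genes (0.13) on leaving out any 1 of the 6. The KO minus WT folds of the 2 control comparisons correlated at 0.74 across genes, with 1413 higher and 1311 lower in both against 486 and 474 if independent. Since both compare the same genotypes, independence is only a reference here.

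After PMA and ionomycin, several cytokine genes were lower in KO than in WT cells. IL2 stood at 66.7 ± 9.69 against 573 ± 4.01 CPM (-3.09 ± 0.098, edgeR Benjamini-Hochberg adjusted p = 2.71e-06), CCL3 at 24.7 ± 4.16 against 172 ± 7.16 CPM (-2.79 ± 0.11), CCL4 at 57.5 ± 11.7 against 387 ± 11.4 CPM (-2.73 ± 0.12), and CSF2, a myeloid growth factor, at 7.05 against 39.4 CPM (-2.46 ± 0.15). Of 27 cytokine genes 16 were lower and 4 higher (17 and 4 adjusted over the list alone; median -1.21; adjusted p = 0.0646 with an estimated correlation). Other markers were mixed. CD69 was level at 618 and 607 CPM (edgeR Benjamini-Hochberg adjusted p = 0.608) and EGR1 was not called (adjusted p = 0.275), IL2RA was higher by 1.26 ± 0.063, TNFRSF9 lower at -1.42 ± 0.062 and GZMB higher by 1.52 ± 0.098. Activation receptors split into 11 higher and 8 lower of 32 (adjusted p = 0.619 with an estimated correlation). TRIM22, an antiviral ligase, was lower at -2.45 ± 0.088, IFI44L at -2.95 ± 0.12 and IFI44 at -2.12 ± 0.072. Interferon-stimulated genes were lower in 29 of 40 (30 adjusted over the list alone; median -0.61; adjusted p = 0.00391 with an estimated correlation). HMGCS1 was lower at -0.72 ± 0.064 and FDPS at -0.78 ± 0.065, and 20 of 25 sterol genes were lower (21 adjusted over the list alone; median -0.47; adjusted p = 0.0111 with an estimated correlation). CDC25A, a cell cycle phosphatase, was lower at -0.67 ± 0.066, with 29 of 40 replication genes lower (30 adjusted over the list alone; adjusted p = 0.0147 with an estimated correlation). TCF7 stood at 80.1 against 17.2 CPM (2.23 ± 0.1), S1PR1, the egress receptor, was higher by 2.14 ± 0.2, and thymocyte genes were higher in 17 and lower in 5 of 33 (17 and 7 adjusted over the list alone; adjusted p = 0.0266 with an estimated correlation). LCP2 and SH2D1A were higher by 1.22 ± 0.061 and 1.25 ± 0.061, and receptor-complex genes higher in 20 and lower in 5 of 34 (21 and 6 adjusted over the list alone; adjusted p = 0.0531 with an estimated correlation). VIM, a filament protein, was higher by 1.66 ± 0.1, with 21 higher and 1 lower of 38 adhesion genes (adjusted p = 0.0936 with an estimated correlation). MAGEA4, RORB, EPHA3 and ENPP1 were higher in KO (4.78 ± 0.18, 3.95 ± 0.17, 3.95 ± 0.18 and 3.79 ± 0.15).

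That comparison of KO and WT cells after PMA changed when 1 library was left out, which also leaves fewer samples. EdgeR called 3848 of 15921 genes, 2099 higher and 1749 lower, but 6626 without replicate 2 of activated KO cells, the library set apart by transcript length. The balance turned without it (3212 higher, 3414 lower), in 1 fit of all 24 libraries (3007 and 3398) and with length and GC trends removed (2692 and 2718, in all 5410). Without WT replicate 1, 2 or 3 edgeR called 2204, 2106 and 2100, nearly alike whichever was left out. The list calls numbered 4, but 8 without KO replicate 2, 3 without WT replicate 3 and 2 without each of the other 4 libraries. Replication genes lost their call without WT replicate 1 or 2 or KO replicate 1 or 3, and thymocyte genes on leaving out any 1 library except KO replicate 2 (adjusted p up to 0.072 for each). Interferon-stimulated and sterol genes kept theirs (up to 0.023 and 0.049). Medians without KO replicate 2 were -1.23 for cytokine and -0.64 for interferon-stimulated genes. Scaling by library size alone gave 2580 higher and 1271 lower in place of 2099 and 1749.

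After CD3 and CD28 antibodies several activation genes were lower in KO than in WT cells, which in part held before stimulation. TRAC stood at 189 against 582 CPM (-1.62 ± 0.03), CD69 at 73.5 against 138 CPM (-0.90 ± 0.062), PDCD1 was lower at -1.84 ± 0.14, TOX2 at -2.64 ± 0.13 and ZBTB16 at -2.49 ± 0.054, while IL2RA was higher by 2.16 ± 0.21. CHI3L2, a chitinase-like protein, stood at 448 against 1880 CPM (-2.06 ± 0.028). Activation receptors were lower in 21 and higher in 6 of 29, checkpoints in 15 and 2 of 29, and receptor-complex genes in 23 and 5 of 34, all unchanged adjusted over the list alone (adjusted p = 0.0170, 0.0170 and 0.0330 with an estimated correlation). TRAC, CD69 and activation receptors were already lower in KO than in WT cells among CD3 controls. The interaction of genotype with CD3 stimulation called none of these 3 lists, so a weaker response of them in KO cells was not shown. Immediate early genes and NF-kB targets were nearly level between activated KO and WT cells (median -0.06 each) and were not called. HMGCS1 stood at 343 against 939 CPM (-1.45 ± 0.031). Sterol genes were lower in 24 of 25, also adjusted over the list alone (median -0.73; adjusted p = 0.00528 with an estimated correlation), and fatty acid genes in 10 with 1 higher of 12 (11 and 1 adjusted over the list alone; adjusted p = 0.0170 with an estimated correlation). GBP2 was lower at -2.03 ± 0.11, XAF1 at -1.57 ± 0.047, and interferon-stimulated genes were lower in 21 and higher in 5 of 37 (22 and 6 adjusted over the list alone; adjusted p = 0.0296 with an estimated correlation). Adhesion genes were lower in 21 and higher in 8 of 37 (21 and 10 adjusted over the list alone; adjusted p = 0.0455 with an estimated correlation). RAG2 and RAG1 were higher by 3.74 ± 0.19 and 3.04 ± 0.11. Mitotic genes were higher in 35 of 38, glycolysis genes in 19 with 1 lower of 24, and hypoxia genes in 14 with 6 lower of 25 (adjusted p = 0.125, 0.172 and 0.0786 with an estimated correlation), BNIP3 by 1.70 ± 0.094. EPHA3 and RORB stood at 53.3 and 109 CPM against 1.61 and 3.83. EdgeR called 7089 of 15179 genes, 3545 higher and 3544 lower, or 4489 and 2744 when scaled by library size alone. Of 7 lists called, 5 were called without KO replicate 3, 4 without WT replicate 3, and 1 without WT replicate 1 or 2. Without KO replicate 1 or 2 the camera calls fell to 0, with the sterol list at an adjusted p of up to 0.055.

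In all 4 comparisons of KO with WT, 563 genes were higher and 327 lower in KO among 14370 tested in each, against 15.1 and 12.2 if the calls were independent. All 4 set the same KO cells against the same WT cells by label, so any lasting difference between them recurs. Independent calls are thus only a reference, and the excess is no test. MAGEA4, a cancer-testis antigen (4.53 to 5.79), CTBP2, a corepressor (3.87 to 4.84), EPHA3 (3.76 to 5.06), RORB (3.56 to 4.83), NECTIN3, an adhesion molecule (3.42 to 4.33), and WT1 (3.04 to 3.75) were higher throughout, as were TMEM132D, RNF182 and ESRP1. PTPRG, a receptor phosphatase, was nearly absent from WT cells, with count ratios of 103 (34.9–501) and 123 (41.6–597) where WT groups held 3 counts. TRIM22 was lower throughout (-2.79 to -2.06), with IFI44 (-2.12 to -1.56), BLK (-2.33 to -1.24), GUCY1A1 (-1.53 to -1.06), TNFSF8 (-1.76 to -0.97), TDRD9 (-2.32 to -0.95), CELSR3 (-1.22 to -0.92) and AADAT (-1.25 to -0.92). AP3B1, a vesicle adaptor subunit, stood at 26.7 to 28.4 CPM in KO and 64.1 to 75.6 CPM in WT groups. Stimulation raised NRIP1 in WT cells from 0.516 to 12.5 CPM with PMA and from 0.556 to 5.26 CPM with CD3 antibodies, while KO cells held 43.6 to 48.0 CPM in every group. Whether the KO cells were a single clone was not stated. Effects of the knockout and of the separate culture of the KO cells cannot be told apart in these libraries.

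**Figure D5:**
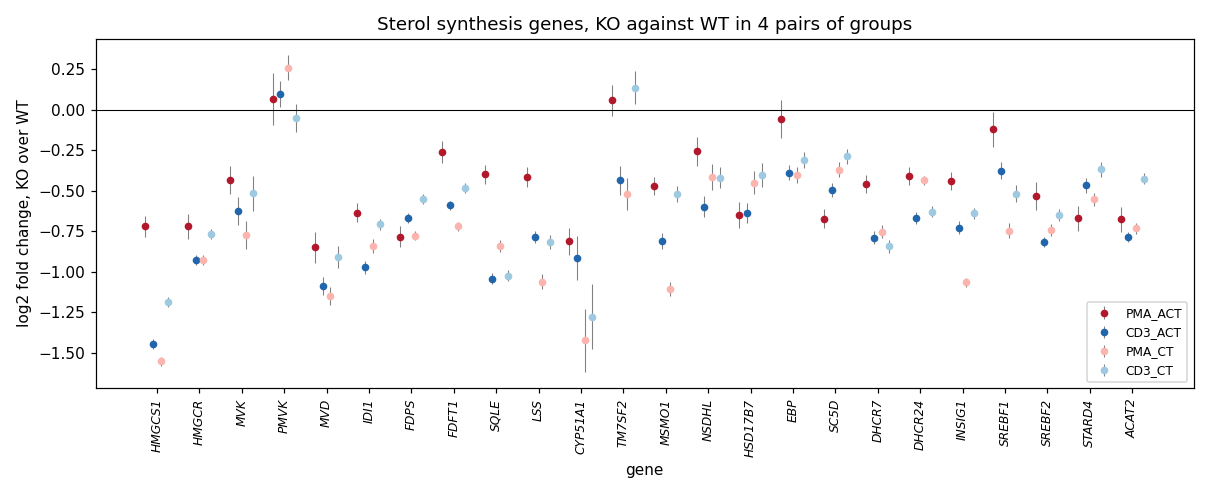
Log2 fold change of KO over WT with SE bars (edgeR, n = 3 per group) for 24 sterol synthesis genes in 4 comparisons. Most points lie under 0, with HMGCS1 at -1.55, -1.19, -0.72 and -1.45.

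Activated cells of both stimuli were also compared directly. In WT cells PMA and ionomycin gave higher CCL4 (at least 6850-fold) and CCL3 (at least 3050-fold), which had 0 counts after CD3 antibodies, and IL2 at a count ratio of 10100 (3470–49200). CD69 was higher by 2.14 ± 0.042 and EGR1 by 3.22 ± 0.039, while ALDH1A2, a retinoic acid enzyme, and TCF7 were lower at -6.79 ± 0.058 and -4.63 ± 0.045. Interferon-stimulated genes were higher in 39 and lower in 1 of 40 and sterol genes in 23 and 1 of 25, whereas 39 of 40 replication genes were lower and 1 higher, the same adjusted over the list alone (adjusted p = 0.00293, 0.00814 and 0.00781 with an estimated correlation). In KO cells CD200 (at least 1310-fold) and CCL4 (at least 1060-fold) were higher with PMA, CD69 by 3.10 ± 0.085, and DNTT was lower at -4.42 ± 0.16. Interferon-stimulated genes were higher in 37 of 39, and 39 of 40 replication genes were lower and 1 higher (adjusted p = 0.00128 and 0.00234 with an estimated correlation). EdgeR called 10272 of 15578 genes in WT (5192 higher, 5080 lower) and 7573 of 15777 in KO cells (4043 higher, 3530 lower), or 6529 and 3940, and 4976 and 2767, when scaled by library size alone. In WT cells heat shock and cytotoxic genes lost their calls on leaving out any 1 of the 6 libraries (adjusted p up to 0.068), and in KO cells presentation genes without PMA replicate 1 or any CD3 library (up to 0.073). Control groups of the PMA and CD3 experiments differed at least 2-fold in 94 genes in WT and 114 in KO cells, against 2677 and 2333 between activated groups. The difference between responses, which takes out that of the controls, was positive for all 40 interferon-stimulated genes in WT cells (also adjusted over the list alone; median 2.27; adjusted p = 3.58e-06 with an estimated correlation).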

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

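Of the tests used for the patterns weighed here, the correlation with transcript length, the share of variance explained by stimulation, the resampling interval, the ratio to libraries of other groups and the count of lists with a larger response in KO cells were chosen only after the result was seen.

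KO and WT cells differed in their response to PMA and ionomycin, as a tested difference between groups (the interaction term of genotype and stimulation) in 2718 genes and 10 gene lists. Whether this came from the knockout or from the separate KO culture cannot be told apart here. VGF, a secreted neuropeptide precursor, rose from 0.173 to 17.1 CPM in KO and from 0.596 to 2.53 CPM in WT cells, an interaction of 4.5 log2. Genes that fell less in KO than in WT cells were IGLL1 (2.88), ALDH1A2 (2.81), PI16 (2.75), S1PR1 (2.56) and TCF7 (2.50), of which TCF7 fell from 470 to 17.2 CPM in WT and from 390 to 80.1 CPM in KO cells. Genes that rose less were PLEK (-4.42), SVEP1 (-4.15), RAI14 (-3.55) and NETO1 (-3.47), where PLEK rose from 0.743 to 62.4 CPM in WT and from 6.63 to 26.0 CPM in KO cells. NRIP1 (-4.65) rose only in WT cells and was already high in KO controls. CD69 (1.23), NR4A1 (1.40) and CD247 (0.54) had positive and EGR1 (-0.67) and MYC (-0.54) negative terms. List medians were 0.40 for activation receptors, 0.32 for checkpoints, 0.62 for receptor-complex genes, 0.30 for sterol synthesis, 0.64 for thymocyte genes and 0.37 for adhesion genes. They were -0.33 for replication genes, -0.15 for endoplasmic reticulum chaperones, -0.32 for ribosome biogenesis and -0.24 for interferon-stimulated genes. The chaperone call was lost without WT control replicate 1, KO activated replicate 1 or 3 or KO control replicate 1 or 3 (adjusted p up to 0.062), and the interferon call without KO activated replicate 2 or KO control replicate 3 (up to 0.075). The number of genes called rose to 4192 without replicate 2 of activated KO cells.

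KO and WT cells also differed in their response to CD3 and CD28 antibodies, again by the interaction term between groups, in 2000 genes and 2 lists. RAG2 (2.01), TSHR (1.61), PDGFC (1.44), CTSG (1.44), DNTT (1.43) and NOTCH3 (1.27) fell less in KO cells, with RAG2 going from 42.9 to 11.6 CPM in KO and from 13.2 to 0.872 CPM in WT cells. NRIP1 (-3.40) and MX2 (-1.51) were called higher only in WT cells, and ENPP1 (-1.74), TP53INP1 (-1.47), LGALS1 (-1.43) and ICA1 (-1.43) rose less in KO cells, with ICA1 going from 5.54 to 39.1 CPM in WT and from 4.73 to 12.7 CPM in KO cells. EGR1 (0.74), NR4A1 (0.78), MYC (0.42) and CD3E (-0.13) were called as well. The heat shock list had a median of 0.19 and the ribosome biogenesis list 0.24. Ribosome biogenesis genes had response medians of -0.38 in WT and -0.13 in KO cells, but activated KO and WT cells were nearly level (-0.09). These genes also stood higher in WT CD3 controls than in WT PMA controls (camera adjusted p = 0.0043 with an estimated correlation). Their term thus carries the level of the WT CD3 controls, and what raised that level was not tested. Only 1 list passed without WT activated replicate 3, WT control replicate 2 or 3, KO activated replicate 1 or KO control replicate 2, and 3 passed without KO activated replicate 2.

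Replicate 2 of activated KO cells in the PMA experiment stood apart from its group, with deviations over genes of SD 0.291 against 0.0756 to 0.105 in other groups. They followed transcript length (Spearman rho across genes of -0.75, genes not being independent replicates), beyond the 0.29 of libraries of other groups, which is consistent with a trend by transcript length; RNA quality itself was not tested. Its mates reached 0.66 and 0.70, above the 0.3 predicted for other libraries, because their reference mean contains this library. With the trend removed its deviation was 1.52 times the largest of the other 23 libraries (1.48–1.56 over 1000 resamples), which spans the 1.5 set beforehand. That largest library was a mate whose reference contains this one. Against the largest of the 21 libraries of other groups the ratio was 1.87, which leans to a further part, but over the same resamples it ran from about that bound to 2.16, so length as the whole of the deviation cannot be told apart from length with a further part. The WT response explained 0.356 percent of the deviation, so a different stimulation likely does not account for it. Markers of other cell types were 1.26 times those of the higher of its mates, so foreign RNA was not borne out by this sum. All libraries held 111 to 171 CPM of these markers, so the sum could not have shown a moderate share of foreign RNA or other cell types.

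Cytokine and interferon-stimulated genes were lower in KO than in WT cells after PMA and ionomycin, with medians of -1.21 and -0.61, although the cytokine list was not called (adjusted p = 0.0646 with an estimated correlation). Without KO replicate 2 the smaller share of a median kept was 101 percent, and with length and GC trends removed 106 percent, so these causes were not borne out by the tests. Interferon-stimulated genes were already lower in KO controls (median -0.39), and their interaction term had a median of -0.24. That interaction call was lost without KO activated replicate 2 or KO control replicate 3 (camera adjusted p up to 0.075). Medians of their PMA responses were 2.55 in KO (39 genes) and 2.47 in WT cells (40 genes). A smaller response of these genes in KO cells was thus not firmly shown. A smaller response in every gene list was not borne out either, since 3 lists called in WT had the larger response in KO cells. These were replication genes (medians of -0.97 in KO and -0.60 in WT), sterol synthesis (1.40 and 1.11) and activation receptors (1.38 and 1.05). Their interaction calls held with each library left out, but of their calls in WT cells only that of sterol synthesis did. Sterol genes were lower in KO than in WT cells both in PMA controls (median -0.75) and after PMA (-0.47). A response smaller on average stays open. The slope of KO on WT responses over genes called in WT cells was 0.86, between the bounds of 0.8 and 0.9 set beforehand. Choosing genes by their WT response can itself lower this slope, so the slope alone does not show a smaller response. For the cytokine genes a response smaller on average cannot be told apart from a specific one. Other activation genes were mixed, with IL2RA higher and TNFRSF9 lower in KO cells. CD69 stood level after PMA, but from a lower level in KO controls, so it rose more in KO cells (interaction of 1.23). The effect of the knockout cannot be told apart from another difference of the KO culture.

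Sterol synthesis genes were lower in KO than in WT cells in all 4 comparisons. With length and GC trends removed at least 97 percent of each median was kept, and under 2 other scalings at least 87.5 percent, so neither likely made the difference. Whether the knockout or the history of the KO culture lowered them cannot be told apart here.

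Other splits of the same libraries were tried for each number of called genes. Splits of 6 libraries number 10, of which 1, the real one, gave as many calls in each of the 12 pairwise comparisons, and these are too few for a share under 0.05. The real numbers were those given for each comparison, and the highest other split gave 0 calls, or 2 for the PMA response of KO cells and for KO controls. For interactions 100 splits were drawn. As many calls came from 2 for genotype with PMA (highest other 4736), 4 for genotype with CD3 stimulation (8830), 2 for stimulus in WT (9203) and 2 for stimulus in KO cells (6794). In each interaction the split with the most calls exchanged all libraries of 1 state and none of the other. That turns the term from the difference into the sum of the group differences in both states, so its count follows from its construction. For genotype with CD3 stimulation 2 further splits (2336 and 2062 calls) exchanged 3 activated libraries and 1 control. By construction their term adds part of the group difference in controls to that in activated cells. How much of their counts this accounts for was not tested.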

How the results depend on the processing

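Most results kept their direction and their side of the threshold. Of the named genes' values, 2090 of 2156 were unchanged in kind with DESeq2, 2159 of 2165 with median-of-ratios scaling, 2130 of 2165 with library size alone, 2130 of 2165 without a filter, 2052 of 2165 in 1 fit of all 24 libraries, 667 of 679 without replicate 2 of activated KO cells in the PMA experiment, and 14720 of 15467 with another library left out. With each library's length and GC trend removed, an alternative chosen after seeing the data, it was 2127 of 2165. Only 2 results reversed. MT-ATP8 in KO cells of the CD3 experiment went to -0.10 with that trend removed (edgeR adjusted p = 0.466 after Benjamini-Hochberg adjustment). CD3E between activated KO and WT cells of the PMA experiment went to -0.08 without KO replicate 2 (adjusted p = 0.0463) and to 0.10 without KO replicate 3. The cause was not tested.

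In 1 fit of all 24 libraries the number of genes called went from 3848 to 6405 for KO against WT after PMA, from 3369 to 1962 between the WT control groups, and from 2000 to 984 for the interaction of genotype with CD3 stimulation. That fit shares 1 spread among all groups. DESeq2 called 1543 in place of 2517 genes between the KO control groups, and the cause was not tested.

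Leaving out single libraries, which also leaves fewer samples, moved the number of genes to 2100–6626 for KO against WT after PMA, 1600–2392 between KO control groups and 1999–4192 for the interaction of genotype with PMA. Lists called went from 15 to 3–14 for PMA in WT, from 10 to 5–8 for CD3 stimulation in KO, from 4 to 2–8 for KO against WT after PMA, from 7 to 0–5 after CD3 stimulation and from 4 to 0–4 in CD3 controls. Between WT controls they went from 5 to 2–6, between KO controls from 1 to 0 with camera each time, and for the interaction of genotype with CD3 from 2 to 1–3.

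With the list correlation preset at 0.01, more lists passed. It gave 19 for CD3 stimulation in WT and 18 in KO cells, and for KO against WT 15 after PMA, 17 after CD3 stimulation, 12 in PMA controls and 17 in CD3 controls. PMA against CD3 gave 21 in activated KO cells, 18 in WT controls and 16 in KO controls, and the interactions of genotype 17 with PMA and 9 with CD3. A preset correlation leaves out most of the dependence between genes, which shows in its construction. With median-of-ratios scaling 2 in place of 4 lists passed for KO against WT in CD3 controls.

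With the replicate number as a block, camera called 0 lists for PMA in WT, for CD3 stimulation in WT and in KO, for the 4 comparisons of KO with WT and for both comparisons of controls. With this block it called 5 and 6 lists for PMA against CD3 in activated WT and KO cells and 1 for the interaction of genotype with CD3. The block takes degrees of freedom from 6 libraries. Same-numbered libraries matched best throughout only in KO cells of the CD3 experiment and between WT controls. In these 2 comparisons the block raised the genes called from 3450 to 3661 and from 3369 to 3793, so a pairing cannot be excluded there.

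Correlations across genes, which are not independent replicates, kept their sign with only genes of at least 5 CPM. They were 0.94 and 0.83 between genotypes for PMA and CD3, 0.62 and 0.71 between stimuli in WT and KO, and 0.39 and 0.76 between the KO to WT differences of activated and of control cells, in place of 0.92, 0.73, 0.59, 0.62, 0.49 and 0.74. With single libraries left out they were 0.91–0.92, 0.68–0.70, 0.56–0.59, 0.57–0.61, 0.46–0.49 and 0.70–0.73 in the same order.

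Scaling by library size alone turned the balance of higher and lower genes in 4 comparisons. It gave 4569 higher and 2525 lower for KO against WT in CD3 controls in place of 3470 and 3568, 2477 and 1256 between WT controls in place of 1445 and 1924, 4363 and 3708 for stimulus in WT cells in place of 3818 and 4268, and 4131 and 2607 for stimulus in KO cells in place of 3240 and 3403. For the interaction of genotype with PMA it tilted the balance further the same way, to 1599 and 1008 from 1375 and 1343, whereas median-of-ratios scaling (1279 and 1480) and DESeq2 (1230 and 1617) turned it. It moved the median of all genes by 0.109 log2 for PMA in KO, 0.115 and 0.101 for PMA against CD3 in activated WT and KO cells, and 0.109 for stimulus in KO cells. At 16012410 to 22846872 counts per library, genes under the floor of 3 counts per group and small changes of weakly expressed genes, such as IL2 after CD3 stimulation, stayed out of reach.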

Other observations

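Controls of the PMA and CD3 experiments differed from each other within each genotype (n = 3 per group). In WT cells ADD3, a membrane skeleton protein, stood at 189 CPM in PMA and 87.4 CPM in CD3 controls (1.13 ± 0.037), EOMES, a T-box factor, was higher by 1.25 ± 0.16, and PLCH1, a phospholipase, stood at 4.25 against 17.4 CPM (-2.03 ± 0.11). Ribosome biogenesis genes were lower in 32 of 34, also adjusted over the list alone (median -0.23; camera adjusted p = 0.00428 with an estimated correlation). Activation receptors were lower in 19 and higher in 1 of 28, the same adjusted over the list alone (adjusted p = 0.00563 with an estimated correlation). In KO cells ALDOC, a glycolytic enzyme, was lower in PMA controls (-1.59 ± 0.14), as was BNIP3, a mitophagy receptor (-1.23 ± 0.12), at 42.2 ± 0.23 against 99 ± 27.4 CPM. Thymocyte genes were lower in 16 and higher in 3 of 34 (16 and 4 adjusted over the list alone; adjusted p = 0.0293 with an estimated correlation), a call lost on leaving out any 1 of the 6 libraries (up to 0.14). Glycolysis genes were lower in 16 and higher in 1 of 24 (adjusted p = 0.241 with an estimated correlation). EdgeR called 3369 of 14884 genes in WT and 2517 of 15190 in KO cells, but only 1610 without KO PMA control replicate 1, and 1600 and 1616 without CD3 control replicate 2 and 3. Since cells without stimulus differed, direct comparisons of the stimuli also carry this difference.

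In the authors' deposited table of pathways, Cytokine-cytokine receptor interaction ranked first for PMA in WT (91 of 284 genes, authors' adjusted p = 2.10e-12) and in KO (81 of 284, 1.73e-09), for CD3 stimulation in KO (17 of 284, 1.15e-05), for activated WT and KO cells of PMA against CD3 (79 of 284, 1.04e-10, and 75 of 284, 9.51e-13) and for KO against WT after PMA (35 of 284, 5.79e-09). For CD3 stimulation in WT and for KO against WT after CD3 stimulation it was Transcriptional misregulation in cancer (26 of 179, 1.00e-08, and 23 of 179, 2.41e-04). Of 3644, 746, 3268 and 261 genes the authors called for PMA and CD3 in WT and for PMA and CD3 in KO cells, 3028, 686, 2872 and 260 were tested here, and all had the same sign. Over the 8 comparisons, between 83.1 and 99.6% of the authors' calls were called here.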
